A study of Drosophila melanogaster with 20 samples.

How the data were processed

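RNA from male heads of 4 groups was analysed, control and chm mutant flies that were fed or starved for 24 h, with 5 libraries per group and 30 heads per library. Per the labels, total RNA was depleted of ribosomal RNA with a kit made for human, mouse and rat, and libraries were made with a directional kit. The authors list STAR 2.5.3a, bedtools 2.27.1 and DESeq2 1.24. The deposited values are raw read counts per gene, not normalised, 1 table per library, and the counts on the strand of the directional kit were used. The genome build and annotation release were not given in the sources used here, so no coordinates are printed, and gene order and chromosome arm came from a reference annotation matched by gene identifier. The tables hold 17481 gene identifiers, of which 138 had no symbol in the name table, 84 of them among the tested genes.

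Depth was 2.02 to 19.8 M gene counts per library, with a median of 8.08 M. Reads listed as unmapped made up 62.8 to 71.4% of all reads. The tables list 0 reads as mapping to several places, so that share could hold such reads, and the sources used here do not say where they went. Reads outside genes made up 3.99 to 5.98% and ambiguous reads 0.748 to 0.994%. No 2 replicates of a group were copies of one another, since the chi-square per gene between replicates was at least 2.25 and at most 17.1. The labels do not say whether replicates came from separate cultures or days, so the p-values measure only the spread between samples.

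Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Genes were kept with the filterByExpr function of edgeR, libraries were scaled by the trimmed mean of M values, and all 20 libraries were fitted together with 4 group terms and a term for sequencing run and lane (3 levels, taken from the names of the deposited tables). Each group had 2 libraries in lane 2 and 2 in lane 3 of the first run and 1 in the second run. Genes were tested with the robust quasi-likelihood F test on 14 residual degrees of freedom, p-values were adjusted by Benjamini-Hochberg within a comparison, and a gene was called at an adjusted p under 0.05. The comparisons were starved against fed in each genotype, mutant against control in each feeding state, and the difference between the starvation responses. The SE of a log2 fold change is its size divided by the square root of F. Agreement between the responses was measured over genes called for their average, with a jackknife over libraries.

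Replicate numbers were checked as pairs by correlating residuals. Mutant fed and starved libraries of one number resembled each other in all 5 pairs (r 0.212 to 0.378), and after removal of run and lane r was -0.281 to 0.148. In controls r was 0.0699 to 0.408, with 3 of 5 pairs over 0.1. Between genotypes r was -0.161 to 0.139 in fed and -0.240 to 0.150 in starved flies, with 1 of 5 pairs over 0.1 in each. Fed and starved libraries of one genotype and number shared run and lane, which the fit includes. The own number was the best match in 5 of 5 mutant pairs and 3 of 5 control pairs, before removal of run and lane. These matches can come from the shared run and lane alone. A pairing beyond run and lane is therefore neither shown nor excluded, and a block for the number was run as an alternative.

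The tests also covered 32 gene lists written before the data were examined, for pathways and for markers of cell types that a head sample could hold. A list with fewer than 3 measured genes was not tested, which left 30. Lists were tested with camera at an inter-gene correlation of 0.01, again with the correlation estimated from the data, and with fry, each adjusted by Benjamini-Hochberg over lists. Lip4, tobi, Gs2, Pdf and to each stood in 2 lists. No list with a called test had a median, mean and test of differing sign. Library measures such as marker shares were compared by exact permutation of the 5 against 5 libraries, whose smallest two-sided p is 0.00794, and adjusted over 60 tests.

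Genes were named by a rule set before the data were examined. It took chm, and for each comparison of 2 groups the 8 highest and 8 lowest log2 fold changes among called genes with a mean log2 CPM of at least 3 and no overlap of the 5 against 5 values. It added the 3 members with the smallest p of each list called by camera, the 10 top called genes of the difference between responses, and examples from the nutrient-response, lipolysis and acetyltransferase lists. Ribosomal RNA genes were left out of the ranked parts. Genes named outside this rule are said to be so. The texts give a selection of the genes the rule named.

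The fit was tested on simulated data of 9784 genes, with 67, 67 and 66 genes changed by 1.25-fold, 1.5-fold and 2-fold. At these true changes it recovered 53.7, 70.1 and 92.4% of changed genes for starvation in controls, 50.7, 89.6 and 95.5% in mutants, 58.2, 73.1 and 92.4% for genotype in fed flies, 58.2, 85.1 and 90.9% in starved flies, and 34.3, 70.1 and 80.3% for the difference between responses. Unchanged genes made up 10 of 154, 3 of 160, 11 of 160, 7 of 163 and 8 of 131 calls in that order. Recovery at an adjusted p depends on how many genes change, so these shares need not hold for the real comparisons.

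Alternatives were DESeq2 size factors, DESeq2 and limma voom as tools, no low-count filter, a filter of at least 1 CPM in 5 libraries (which kept 9972 genes, more than filterByExpr), no run and lane term, run alone, the replicate number as a block, the 10 libraries of a comparison alone, no second run, both strands counted together, no ribosomal RNA or mitochondrial genes, a test against a 1.2-fold change, and each library left out in turn. No sample was excluded. Calls were also compared with those from 100 splits of the samples per comparison.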

Results

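Gene expression was measured by RNA sequencing in heads of male Drosophila melanogaster carrying a mutation in chameau (chm), which encodes a histone acetyltransferase of the MYST family, and in heads of wild-type control males. Flies of each genotype were either fed or given water without food for 24 h, which made 4 groups of 5 libraries each. Each library came from 30 heads of flies aged 8 to 9 days and held at 23 °C. The reads assigned to genes ranged from 2.02 M in control fed replicate 1 to 19.8 M in mutant starved replicate 3, with a median of 8.08 M. In all, 9784 genes were abundant enough to be tested. Feeding accounted for 93.2% of the variance of the first principal component, which held 20.2% of all variance. The second component held 13.6%, and 90.3% of its variance lay between the 2 sequencing runs. On the third, which held 11.2%, control fed replicate 1 stood apart at 31.0, with all other libraries from -8.52 to 11.2.

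The chm transcript (FBgn0028387) was lower in every mutant library than in any control library. It stood at 22.6 ± 1.02 CPM (counts scaled to library size; mean ± SD, n = 5) in control fed heads and 14.8 ± 1.11 in mutant fed heads, a log2 fold change of -0.58 ± 0.09 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00117). In starved heads it was 24.0 ± 2.60 in controls and 15.7 ± 1.90 in mutants, a log2 fold change of -0.62 ± 0.08 (edgeR adjusted p = 3.37e-05). Starvation itself left chm without a called change, at 0.11 ± 0.08 in controls and 0.07 ± 0.08 in mutants on the log2 scale. In lane 2 of the first run the means of control fed, control starved, mutant fed and mutant starved heads were 22.1, 23.0, 15.3 and 13.7 CPM, and in lane 3 they were 22.5, 25.8, 14.9 and 17.3 CPM. The second run held 1 library per group, at 23.8, 22.5, 13.6 and 16.3 CPM. The labels do not state the lesion, so a gene-level count shows the amount of transcript and not whether its acetyltransferase domain was intact.

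**Figure D1:**
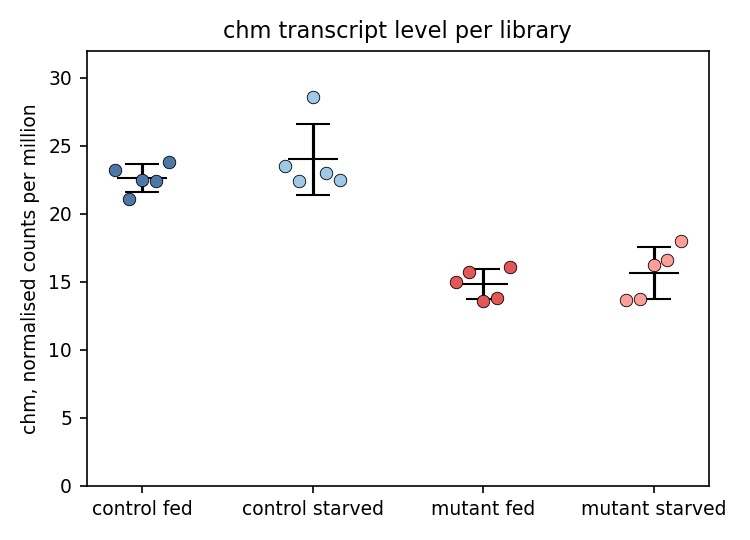
Normalised chm expression in CPM (vertical axis) in each of the 20 libraries, by group (horizontal axis); points are libraries, the horizontal line is the group mean and the bars are 1 SD. The 10 mutant libraries lie below the 10 control libraries, with group means of 22.6 and 24.0 in controls and 14.8 and 15.7 in mutants.

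The first comparison asked which transcripts starvation changed in control heads. The steepest falls were in fit, a satiety peptide of the fat body, and in the storage protein gene Lsp2. fit fell from 78.1 ± 20.2 to 3.45 ± 0.532 CPM, a log2 fold change of -4.54 ± 0.29. Lsp2 fell from 17390 ± 1245 to 2105 ± 267 CPM, a log2 fold change of -3.04 ± 0.13. Gnmt, whose enzyme methylates glycine with S-adenosylmethionine, fell by 2.37 ± 0.21 on the log2 scale, and Nmdmc, a mitochondrial one-carbon enzyme gene, fell by 2.13. tobi, an alpha-glucosidase gene controlled by insulin and glucagon-like signals, fell by 1.88, and the storage protein gene Lsp1beta fell by 1.85. Transcripts that rose included those of the predicted lipase CG5966 (log2 fold change 2.45 ± 0.10), the secreted phospholipase GIIIspla2 (1.94 ± 0.09), the insulin-suppressing hormone limostatin, Lst (1.36 ± 0.09), and sarcosine dehydrogenase, Sardh (1.31 ± 0.11). In all, 1205 genes changed, 484 upward and 721 downward, of which 71 changed more than 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg). Within lane 2 and lane 3 of the first run, with 2 libraries per group each, 388 and 637 genes were called.

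Genes of lipid breakdown rose as a group in starved control heads. Of 18 measured genes for lipolysis and beta-oxidation, 11 rose, 3 fell and 4 were not called (13 and 3 adjusted over the list alone), and the list rose against other genes (camera adjusted p = 2.27e-20, and adjusted p = 0.000855 with an estimated correlation). The triglyceride lipase gene bmm rose by 0.88 on the log2 scale, the lipid-droplet gene Lsd-2 by 0.53, the acyl-CoA dehydrogenase gene Mcad by 0.57, and whd, the carnitine palmitoyltransferase gene, by 0.55. The members that fell were the perilipin gene Lsd-1 at -0.55, the acyl-CoA dehydrogenase gene CG3902 at -0.46 and the peroxisomal oxidase gene Acox57D-p at -0.26.

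Fat body markers all moved downward. Each of the 11 measured markers fell (11 adjusted over the list alone; camera adjusted p = 2.88e-30, and adjusted p = 0.000309 with an estimated correlation), from fit at -4.54 and Lsp2 at -3.04 to apolpp, a lipoprotein gene, at -0.59 and Apoltp, named here after its values were seen, at -0.16. Together the markers took 4.13 ± 0.258% of gene counts in control fed heads and 1.96 ± 0.143% in control starved heads. The groups did not overlap (exact two-sided permutation test, p = 0.00794). That is the smallest p this design allows, and it was 0.0680 after Benjamini-Hochberg adjustment over 60 tests of library measures. Lsp2 alone took 1.71% of counts in fed and 0.215% in starved control heads, most of the loss. The share fell from 3.93 to 2.04% in lane 2 and from 4.37 to 1.99% in lane 3 of the first run, and from 4.06 to 1.72% in the second run, which held 1 library per group. Of 40 glutathione and antioxidant genes, 15 fell and 4 rose (19 and 4 adjusted over the list alone; camera adjusted p = 2.93e-10, and adjusted p = 0.00335 with an estimated correlation). Among them were GstE7 at -1.32, the peroxiredoxin gene Prx6c at -0.89 and GstE3 at -0.73.

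A further 7 lists were called in control heads at the preset correlation but not with an estimated one. Haemocyte markers had 8 of 10 genes lower and none higher (8 adjusted over the list alone; camera adjusted p = 6.42e-07, and adjusted p = 0.0883 with an estimated correlation). Among them were the matrix genes Ppn at -0.28, Col4a1 at -0.32 and Pxn at -0.27. Oxidative phosphorylation genes had 19 of 34 lower and none higher (22 adjusted over the list alone; 4.61e-08, and adjusted p = 0.286 with an estimated correlation), all by small amounts, such as ATPsynB at -0.25. Ribosomal protein genes had 13 of 77 lower and 1 higher (26 and 1 adjusted over the list alone; 1.10e-05, and adjusted p = 0.513 with an estimated correlation). The unfolded protein and ATF4 list had 4 of 14 lower and 1 higher (4 and 1 adjusted over the list alone; 0.00250, and adjusted p = 0.322 with an estimated correlation). The steepest fall in it was that of asparagine synthetase, AsnS, at -1.37 ± 0.07. Amino acid and one-carbon genes had 9 of 21 lower and 4 higher (10 and 4 adjusted over the list alone; 0.0205, and adjusted p = 0.323 with an estimated correlation). The aminotransferase genes Got2 and Oat stood at 0.66 and -0.66. Antimicrobial peptides and Bomanins had 6 of 20 higher and 2 lower (7 and 2 adjusted over the list alone; 7.55e-05, and adjusted p = 0.278 with an estimated correlation). BomS2 rose by 0.99, BomS6 by 0.86 and BomBc2 by 0.86. Glial markers had 5 of 11 lower and 1 higher (8 and 1 adjusted over the list alone; 0.0178, and adjusted p = 0.286 with an estimated correlation), with Gs2 at -0.32, Eaat1 at -0.17 and the citrate transporter gene Indy at 0.36.

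Of 16 nutrient-response genes of the insulin, TOR and FOXO pathways, 4 rose and 4 fell in control heads (5 and 4 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.490, with a median of 0.05 and a mean of -0.00 on the log2 scale). The insulin receptor gene InR rose by 0.53, Lip4 by 0.83 and chico by 0.23, and Thor, the gene of the translation repressor 4E-BP, rose by 0.47 (edgeR adjusted p = 0.0276). tobi, ImpL2 (-0.23), chrb (-0.19) and scyl (-0.17) fell. Of 19 acetyltransferase and deacetylase genes only Gcn5 was called, at 0.20 (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.168). Fatty acid and triglyceride synthesis had 4 of 13 genes lower and 2 higher (4 and 3 adjusted over the list alone; camera adjusted p = 0.0991). No gene of 18 neuron or 19 muscle markers was called in control heads, and 1 of 23 photoreceptor markers was.

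With a test against a 1.2-fold change in place of any change, 240 genes remained called in control heads.

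The second comparison asked the same of mutant heads. fit fell from 88.7 ± 23.4 to 4.06 ± 0.818 CPM (log2 fold change -4.50 ± 0.26), Lsp2 from 16880 ± 3180 to 2651 ± 355 CPM (-2.67 ± 0.13), and Gnmt from 42.7 ± 12.8 to 9.30 ± 4.03 CPM (-2.20 ± 0.26). Nmdmc fell by 1.91, CG3999 by 1.92 and the phosphoserine phosphatase gene aay by 1.61 on the log2 scale. CG5966 rose by 2.82 ± 0.10, Lst by 1.43 ± 0.08, mino, which encodes a glycerol-3-phosphate acyltransferase, by 1.23 ± 0.06, and Sardh by 1.21 ± 0.11. In all, 1110 genes changed, 445 upward and 665 downward, of which 67 changed more than 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg).

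Lipid breakdown genes rose as a group in mutant heads too, with 13 of 18 higher and 2 lower (14 and 2 adjusted over the list alone; camera adjusted p = 3.17e-32, and adjusted p = 0.000202 with an estimated correlation). bmm rose by 0.98, Mcad by 0.63, whd by 0.66 and Lsd-2 by 0.57 on the log2 scale, while Lsd-1 at -0.47 and CG3902 at -0.33 fell. Fat body markers had 8 of 11 genes lower and none higher (11 adjusted over the list alone; 3.11e-25, and adjusted p = 0.000289 with an estimated correlation). Their share of counts fell from 4.02 ± 0.382 to 1.95 ± 0.150% (n = 5 each; exact two-sided permutation test, p = 0.00794, the smallest possible, and 0.0680 adjusted over the 60 tests). Within the 2 lanes of the first run the share went from 4.05 to 1.89% and from 4.28 to 2.09%, and in the second run from 3.43 to 1.77%. Glutathione and antioxidant genes had 16 of 40 lower and 2 higher (17 and 3 adjusted over the list alone; 1.29e-07, and adjusted p = 0.00934 with an estimated correlation). They included Gclm, a subunit gene of the enzyme that begins glutathione synthesis, at -1.04 and GstE7 at -1.31. Haemocyte markers had 9 of 10 lower and none higher (10 adjusted over the list alone; 2.17e-08, and adjusted p = 0.0398 with an estimated correlation), with Col4a1 at -0.40 and Ppn at -0.32.

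The other called lists in mutant heads lost their call with an estimated correlation. Oxidative phosphorylation had 14 of 34 genes lower and none higher (19 adjusted over the list alone; camera adjusted p = 4.37e-06, and adjusted p = 0.443 with an estimated correlation), with COX6B at -0.18. The unfolded protein and ATF4 list had 5 of 14 lower and 1 higher (5 and 1 adjusted over the list alone; 0.000185, and adjusted p = 0.347 with an estimated correlation), with AsnS at -1.18 and CaBP1 at -0.42. Ribosomal protein genes had 2 of 77 lower and none higher (1 adjusted over the list alone; 0.00607, and adjusted p = 0.686 with an estimated correlation). Glial markers had 5 of 11 lower and 1 higher (7 and 1 adjusted over the list alone; 0.0423, and adjusted p = 0.443 with an estimated correlation), with Indy at 0.46 and Gs2 at -0.28. Bomanins and antimicrobial peptides, with 5 of 20 higher and 2 lower (6 and 4 adjusted over the list alone), and amino acid and one-carbon genes, with 4 of 21 higher and 10 lower (4 and 10 adjusted over the list alone), were not called as lists (camera adjusted p = 0.0547 and 0.217). The nutrient-response list had 3 of 16 higher and 4 lower (3 and 4 adjusted over the list alone; camera adjusted p = 0.773, with a median of 0.03 and a mean of -0.02). Thor stood at 0.22 (edgeR adjusted p = 0.334). Fatty acid and triglyceride synthesis had 3 of 13 higher and 5 lower (4 and 5 adjusted over the list alone; camera adjusted p = 0.264). Gcn5 was again the one called gene of 19 acetyltransferases and deacetylases, at 0.25 (1 adjusted over the list alone; camera adjusted p = 0.366). Photoreceptor, neuron and muscle markers had 4 of 23, 1 of 18 and 1 of 19 genes lower.

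Within lane 2 and lane 3 of the first run 375 and 439 genes were called in mutant heads, and the test against a 1.2-fold change left 221. Without a term for run and lane the mutant count was 738 (edgeR).

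The third comparison asked whether the starvation response differed between the genotypes, and among called genes the 2 responses were close in direction and size. Of the 1205 and 1110 genes called, 756 were shared, 273 of them higher in both and 483 lower in both, with none in opposite directions. Independent lists of these sizes would share 22.0 higher and 49.0 lower genes. Over 2116 genes called for the average of the 2 responses, which share no library, Pearson's r across genes was 0.934 with a jackknife SE over libraries of 0.0165, Spearman's rho was 0.932, and 2110 had the same sign. The slope of the mutant on the control response was 0.983 with a jackknife SE of 0.0889, so neither a somewhat weaker nor a somewhat stronger mutant response was excluded. Genes are not independent replicates, and over all 9784 genes r was 0.706. The choice of the 2116 genes favours agreement, since opposite responses average toward no change and seldom enter the set. Of the 1559 genes called in either genotype, a choice that does not use the average, 1517 had the same sign.

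The direct test of a difference between the responses called 1 gene, CG3699, which went from 62.6 ± 3.90 to 59.0 ± 10.1 CPM with starvation in controls and from 58.5 ± 5.17 to 77.2 ± 10.7 CPM in mutants (difference of log2 fold changes 0.50 ± 0.09; edgeR adjusted p = 0.0274). With the replicate number as a block its adjusted p was 0.0854 in edgeR, and no gene was called. The unadjusted p was under 0.05 for 395 genes, fewer than 1 in 20 of those tested. DESeq2 and limma voom each called 1 gene. The count was 0 without any 1 library except control fed replicate 5, control starved replicate 1 or 2, mutant fed replicate 4 and mutant starved replicate 2, whose removal left 1. It was also 0 within each lane of the first run, without the run and lane term, and without the second run.

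At the preset correlation 4 lists differed in their response, though none of their members was called, over all genes or adjusted over the list alone. The response was more positive in mutants for lipolysis and beta-oxidation (camera adjusted p = 0.00221, and adjusted p = 0.926 with an estimated correlation) and for ribosomal proteins (0.0343, and adjusted p = 0.978 with an estimated correlation). It was more negative for antimicrobial peptides and Bomanins (0.00702, and adjusted p = 0.926 with an estimated correlation) and for neuron markers (0.0343, and adjusted p = 0.975 with an estimated correlation). The median difference of log2 fold changes was 0.06, 0.04, -0.18 and -0.05 in these lists.

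**Figure D2:**
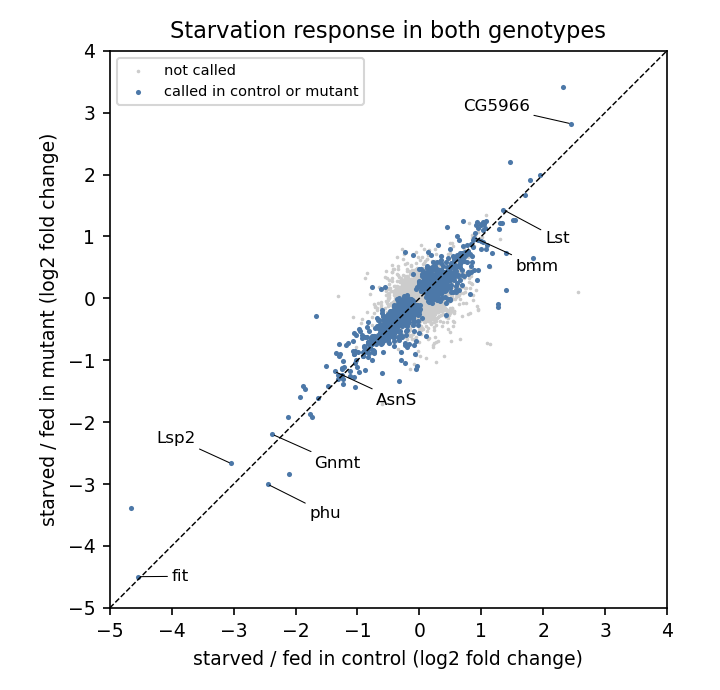
Log2 fold change of starved against fed heads in controls (horizontal axis) and mutants (vertical axis) for 9784 genes; blue points are genes called in either genotype and the dashed line marks equal responses. Called genes lie along that line from fit (-4.54 and -4.50) to CG5966 (2.45 and 2.82), and none of the 756 genes called in both has opposite signs.

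The fourth comparison set mutant against control heads of fed flies. Gnmt differed most among the more abundant genes, at 157 ± 54.0 CPM in controls and 42.7 ± 12.8 CPM in mutants (log2 fold change -1.82 ± 0.20; edgeR adjusted p = 0.00125). Other genes of amino acid and one-carbon metabolism that were lower in mutants were Gs1, a glutamine synthetase gene, at -0.20 ± 0.04, and Sam-S, which encodes the enzyme that makes S-adenosylmethionine, at -0.18 ± 0.04. chm stood at -0.58 and Dpp10 at -0.23 ± 0.04. Higher in mutants were CG42329 (0.49 ± 0.09), CG17739 (0.41 ± 0.07) and Pih1D1 (0.29 ± 0.05). In all, 36 genes were called, 19 higher and 17 lower in mutants, and 817 had an unadjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg).

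Amino acid and one-carbon genes were lower in fed mutant heads as a list, with 3 of 21 called lower and none higher (3 adjusted over the list alone; camera adjusted p = 8.94e-05, and adjusted p = 0.220 with an estimated correlation). Of the 3, Sam-S and Gs1 lay close together on arm 2L, at -623 and -618 tested genes from chm. Genotype calls were concentrated on that arm, as described below, so these calls cannot be told apart from location. Lipolysis and beta-oxidation genes were lower too, by a median of 0.07 on the log2 scale, with none of 18 called (6 lower adjusted over the list alone; 6.84e-06, and adjusted p = 0.220 with an estimated correlation). CG5966 stood at -0.38 (edgeR adjusted p = 0.213) and Acox57D-p at -0.23 (edgeR adjusted p = 0.152). The Turandot stress peptides (0 of 4 called, 0 adjusted over the list alone; 0.00431, and adjusted p = 0.427 with an estimated correlation) were higher as a list. So were photoreceptor markers (0 of 23, and 0 over the list alone; 0.0444, and adjusted p = 0.630 with an estimated correlation) and neuron markers (0 of 18, and 0 over the list alone; 0.0444, and adjusted p = 0.666 with an estimated correlation). Muscle markers were lower as a list (0 of 19, and 0 over the list alone; 0.00421, and adjusted p = 0.639 with an estimated correlation). GstE3, named here after its values were seen, was the one called gene of 40 in the glutathione list, at -0.32 (1 adjusted over the list alone; edgeR adjusted p = 0.0124), and chm the one of 19 acetyltransferases and deacetylases. None of the 16 nutrient-response genes was called, over all genes or adjusted over the list alone.

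The fed genotype count moved when single libraries were left out, also starved ones that are not part of the comparison. Its highest value was 49, without mutant starved replicate 2. It was 15, 19, 14, 21 and 12 without control fed replicates 1 to 5, 22, 22 and 19 without control starved replicates 1, 2 and 4, 14, 15 and 9 without mutant fed replicates 1, 3 and 5, and 16 and 18 without mutant starved replicates 4 and 5 (edgeR). chm, Gnmt, Dpp10, CG42329, CG17739 and Pih1D1 were called without any 1 library. Gs1 was not called without control fed replicate 3 or mutant fed replicate 5 (edgeR adjusted p = 0.0567 and 0.0700). Sam-S was not called without control fed replicates 1, 3 or 5, mutant fed replicates 1, 3, 4 or 5, or mutant starved replicates 4 or 5 (edgeR adjusted p from 0.0522 to 0.184). Within lanes 2 and 3 of the first run the counts were 16 and 38, with the replicate number as a block 20, without the second run 9, without the run and lane term 4, with run alone 9, with limma voom 15, with DESeq2 55 and against a 1.2-fold change 1. Without the run and lane term CG17739, Pih1D1, Dpp10, Gs1 and Sam-S were not called (edgeR adjusted p = 0.160, 0.126, 0.160, 0.160 and 0.173). With the block CG17739, Pih1D1 and Sam-S were not called (0.185, 0.0760 and 0.135), and without the second run CG17739, CG42329 and Sam-S were not (0.0805, 0.0525 and 0.288). In a fit of the 10 fed libraries alone Gnmt and Sam-S were not called (0.0531 and 0.0615). Sam-S was also not called with run alone (0.0703) or limma voom (0.0507).

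The fifth comparison set mutant against control heads of starved flies. Gnmt was again lower, at 29.6 ± 9.97 CPM in controls and 9.30 ± 4.03 CPM in mutants (log2 fold change -1.64 ± 0.27; edgeR adjusted p = 0.0176), as were chm at -0.62 and CG34398 at -0.25 ± 0.05. obst-E, which encodes a chitin-binding protein, was higher at 0.49 ± 0.10, CG31205 at 0.27 ± 0.04, and Gpdh1, the glycerol-3-phosphate dehydrogenase gene, at 0.40 ± 0.08. In all, 32 genes were called, 19 higher and 13 lower, and 825 had an unadjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). Of the 36 and 32 genes called in fed and starved heads, 8 were shared, 4 higher and 4 lower, where independent lists would share 0.0369 and 0.0226.

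In starved heads 9 lists differed between the genotypes at the preset correlation, and none did with an estimated one. The nutrient-response list was lower in mutants with none of 16 genes called, over all genes or over the list alone (camera adjusted p = 0.00672, and adjusted p = 0.548 with an estimated correlation). ImpL2 stood at -0.14 and Lip4 at -0.22. Fatty acid and triglyceride synthesis was higher with Gpdh1 called of 13 genes (1 adjusted over the list alone; 0.0219, and adjusted p = 0.548 with an estimated correlation). Oxidative phosphorylation was higher with none of 34 called, or over the list alone (0.00672, and adjusted p = 0.609 with an estimated correlation). Turandot peptides were higher (0 of 4, and 0 over the list alone; 0.00672, and adjusted p = 0.548 with an estimated correlation), with TotM at 1.42 ± 0.63. Heat shock genes were lower (0 of 13, and 2 adjusted over the list alone; 0.00680, and adjusted p = 0.548 with an estimated correlation), with Hsp68 at -0.57. The unfolded protein list was lower (0 of 14, and 1 adjusted over the list alone; 0.0110, and adjusted p = 0.548 with an estimated correlation), with trbl at -0.32. Muscle markers (0 of 19, and 0 over the list alone; 0.00461, and adjusted p = 0.609 with an estimated correlation) and haemocyte markers (0 of 10, and 1 adjusted over the list alone; 0.0200, and adjusted p = 0.548 with an estimated correlation) were lower. Glial markers were higher (0 of 11, and 0 over the list alone; 0.0314, and adjusted p = 0.548 with an estimated correlation). Digestive enzyme transcripts of the midgut, a trace of all counts, took a larger share in mutants, at 0.0716 ± 0.00690 against 0.0801 ± 0.00439% in fed heads. In starved heads it was 0.0771 ± 0.00166 against 0.0876 ± 0.00782% (exact two-sided permutation tests, n = 5 each, p = 0.0476 and 0.0317, and 0.286 and 0.212 adjusted over 60 tests).

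The starved genotype count also moved with single libraries. It was 98 without mutant starved replicate 2, 18, 19 and 15 without mutant starved replicates 1, 3 and 4, and 15 without control starved replicate 3 or 4 (edgeR). Gnmt was not called without control starved replicate 4, mutant starved replicate 3 or mutant starved replicate 4 (edgeR adjusted p = 0.0578, 0.0664 and 0.0519). CG34398 was not called without control starved replicate 4 or mutant starved replicate 4 (0.0578 and 0.0519), nor obst-E without control starved replicate 3 (0.0843). Gpdh1 was not called without control starved replicates 2, 3, 4 or 5 or mutant starved replicates 3, 4 or 5 (edgeR adjusted p from 0.0700 to 0.149). Within lanes 2 and 3 of the first run the counts were 18 and 63, without the run and lane term 10, with DESeq2 59 and against a 1.2-fold change 1. Gnmt was also not called without the run and lane term, with the replicate number as a block, without the second run, in a fit of the 10 starved libraries alone or against a 1.2-fold change (edgeR adjusted p = 0.149, 0.161, 0.109, 0.0714 and 0.103). Gpdh1 was not called without the second run or in the fit of 10 libraries (0.180 and 0.152).

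The genes that differed between the genotypes lay unevenly over the chromosomes. Besides chm itself, 59 genes were called in fed or starved heads and placed on an arm, and 33 of them lay on 2L, the arm that carries chm. These were 33 of 1731 tested genes (1.91%) on 2L, against 12 of 1988 on 2R, 3 of 1878 on 3L, 9 of 2384 on 3R, 0 of 90 on the fourth chromosome and 2 of 1607 on X. With chm left out, the odds of a call on 2L were 5.92 times those on the other arms (95% interval 3.43 to 10.3; Fisher's exact test, p = 5.04e-11). Fisher's test treats neighbouring genes as independent. A permutation test that kept gene order and rotated the calls gave p = 0.0089 for the 200 tested genes on each side of chm, and 0.0415 for 50 on each side. Dpp10, CG42329, Pih1D1, obst-E, Gpdh1, Gs1, Sam-S and CG34398 lay on 2L, CG17739 on 2R, and Gnmt and CG31205 on 3R.

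**Figure D3:**
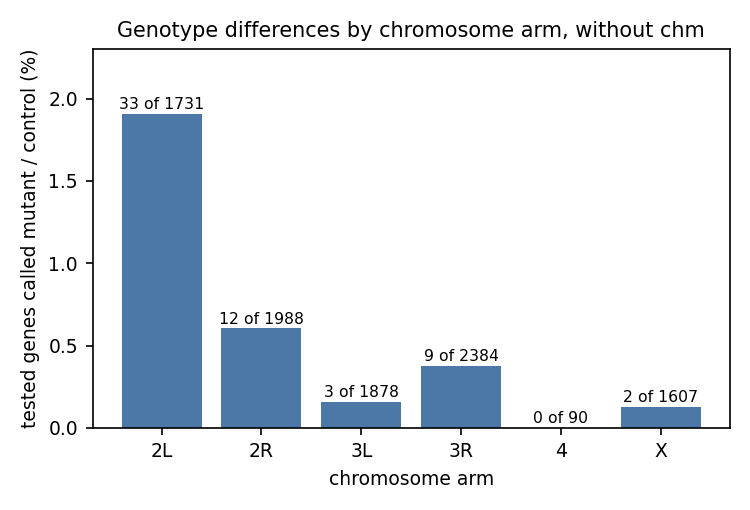
Percent of tested genes on each chromosome arm that were called between mutant and control in fed or starved heads (vertical axis), by arm (horizontal axis), with the number called and tested above each bar and chm left out. Arm 2L holds 33 of the 59 genes, 1.91% of its tested genes.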

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

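All the values in this part were picked by rules set before the data were examined, and no explanation of them was tested. A library was picked where its gap to the nearest other replicate took more than 0.71 of the range of its group. Of 166 groups examined 14 (8.43%) had such a library, where chance alone picks about 5%. Depth, shares and CPM were not corrected for run and lane, and each group held 1 library of the second run. Of the 14 cases, mutant fed replicate 3 held 4 and control fed replicate 5 held 2. Control starved replicate 5 and mutant starved replicate 3 held 1 each. All of these libraries came from the second run, so the excess over 5% cannot be told apart from run. The 166 include the positions of libraries between control and mutant described below, a measure chosen after the data were seen. None of those positions was picked.

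Depth was 2.02 M gene counts in control fed replicate 1 and 19.8 M in mutant starved replicate 3, each far from the other replicates. The 10 most abundant genes took 10.5% of counts in mutant fed replicate 3, which held 4 of the 14 cases. In that library CG5966 was at 118 CPM (other replicates 88.8 to 95.5), GIIIspla2 at 10.4 (15.2 to 17.1) and CG3999 at 85.7 (60.3 to 67.5).

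Among control fed libraries, CG34166 was at 179 CPM in replicate 2 (other replicates 261 to 287), and MsrA at 91.8 (48.2 to 58.0) and Tmem214 at 116 (126 to 130) in replicate 5. Among control starved libraries, CG4757 was at 50.5 CPM (at most 22.9) and cer at 50.5 (41.8 to 43.3) in replicate 1, chm at 28.6 (22.4 to 23.6) in replicate 3, phu at 7.89 (5.22 to 5.98) in replicate 4 and CG11044 at 14.2 (9.52 to 10.8) in replicate 5. The value of chm lay above those of its group, away from the mutant libraries.

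A test of the difference between the starvation responses called CG3699 (difference of log2 fold changes 0.50; edgeR adjusted p = 0.0274) and 4 gene lists. CG3699 was not called with the replicate number as a block (edgeR adjusted p = 0.0854), nor in 15 of the 20 fits that left out 1 library. Those that kept a call left out control fed replicate 5, control starved replicate 1 or 2, mutant fed replicate 4 or mutant starved replicate 2. The lists were lipolysis and beta-oxidation (camera adjusted p = 0.00221), antimicrobial peptides and Bomanins (0.00702), ribosomal proteins (0.0343) and neuron markers (0.0343). With an estimated correlation their adjusted p was 0.926, 0.926, 0.978 and 0.975.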

How the results depend on the processing

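No result changed direction past its threshold under any alternative run. Of 151 gene results, leaving out 1 library gave 2812 unchanged calls, 196 lost and 12 gained, and the other alternatives gave 1784 unchanged, 170 lost and 6 gained. List calls were unchanged in 88 cases and lost in 60.

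Leaving out 1 library gave 977 to 1274 calls for starvation in controls, 925 to 1192 in mutants, 9 to 49 for genotype in fed and 15 to 98 in starved flies, and 0 to 1 for the difference between responses. Agreement between the responses ranged from r = 0.921 to 0.937 and the slope from 0.953 to 1.04.

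Against a 1.2-fold change the 5 counts were 240, 221, 1, 1 and 0, since that test asks for larger effects. Without the run and lane term they were 738 for starvation in mutants, 4 and 10 for genotype and 0 for the difference, with 2 lists called for the difference. With run alone, genotype in fed flies gave 9 and the difference 0. With the replicate block these gave 20 and 0, and without the second run, which leaves fewer samples, 9 and 0. Genotype in fed flies gave 15 with limma voom and 55 with DESeq2, and genotype in starved flies 59 with DESeq2. With an estimated correlation 3, 4, 0, 0 and 0 lists were called in place of 10, 8, 6, 9 and 4. With fry 16 were called for starvation in controls and 0 for genotype in fed flies, genotype in starved flies and the difference. Against a 1.2-fold change chm in fed flies was no longer called (edgeR adjusted p = 0.226). Apart from the 1.2-fold test and the removal of samples, the cause was not tested.

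Of the smallest simulated differences between responses 34.3% were recovered. Depth and the number of changed genes were not varied in that simulation, so how far they limit recovery was not tested.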

Other observations

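All tests of explanations and the splits in this part were chosen after the results were seen. The genes named in the next 2 paragraphs were also chosen after their values were seen.

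Among hormone genes, CCHa2, which encodes a nutrient-responsive peptide, fell with starvation from 721 to 290 CPM in controls and from 818 to 346 CPM in mutants (log2 fold changes -1.32 ± 0.11 and -1.24 ± 0.10; edgeR). The insulin-like peptide gene Ilp5 fell by 0.48 ± 0.09 and 0.32 ± 0.08, and the adipokinetic hormone receptor gene AkhR by 0.23 in both. Of 18 neuropeptide genes 3 fell in each genotype (3 adjusted over the list alone; camera adjusted p = 0.168 and 0.233). Of 66 cytochrome P450 genes, 13 rose and 8 fell in controls and 11 rose and 7 fell in mutants (16 and 14, and 14 and 9, adjusted over the list alone; camera adjusted p = 0.545 and 0.415), with Cyp6t3 at 1.51 and 1.26 and Cyp305a1 at -0.55 and -0.44.

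Sugar digestion and storage had 5 of 14 genes higher and 3 lower in controls, and 5 and 2 in mutants (6 and 3, and 6 and 2, adjusted over the list alone; camera adjusted p = 0.241 and 0.217), with Mal-A5 at 0.40 and 0.41. Amy-p and Amy-d are near-identical copies genes, and their values (Amy-d 0.72 and 0.69) are uncertain. Clock genes had 2 of 12 lower (3 lower, and 1 higher and 3 lower, adjusted over the list alone; camera adjusted p = 0.241 and 0.233), with cwo at -0.55 and -0.51. Odorant-binding proteins had 2 of 23 higher and 3 lower in controls and 1 and 3 in mutants (3 and 3, and 3 and 5, adjusted over the list alone; camera adjusted p = 0.721 and 0.612), with Obp99b at -1.30 and -0.94. Of 4 Turandot genes 2 fell in each genotype (2 adjusted over the list alone; camera adjusted p = 0.0537 and 0.0547), TotA at -0.84 and -0.87 and TotX at -0.88 and -1.15.

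Other lists without a camera call for starvation were glycolysis (13 genes; adjusted p = 0.726 in controls and 0.457 in mutants), ribosome biogenesis (19; 0.942 and 0.442), autophagy (22; 0.168 and 0.257), heat shock (13; 0.965 and 0.257), JNK signalling (13; 0.726 and 0.460), photoreceptor (23; 0.473 and 0.233), neuron (18; 0.729 and 0.0823), muscle (19; 0.490 and 0.366), yolk and eggshell (4; 0.595 and 0.612), mitochondrially encoded genes (19; 0.152 and 0.233) and histones (5; 0.729 and 0.656). Midgut and male reproductive markers had 2 and 1 measured genes and were not tested. Counts on the opposite strand took 4.01 ± 0.153% in control fed and 2.86 ± 0.0958% in control starved libraries, and 4.08 ± 0.313 and 2.94 ± 0.0766% in mutants (exact permutation tests, n = 5 each, p = 0.00794, the smallest possible, and 0.0680 adjusted over 60 tests).

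Genotype calls were concentrated on 2L, the arm of chm. They were common within 200 tested genes of chm, at 15 of 400, and farther along the arm 18 of 1330 genes were called, with odds 4.18 times those on the other arms, with a lower 95% bound of 2.15, which argues against an effect limited to the 200 genes on each side as far as neighbouring genes are independent (a permutation test that kept gene order by rotation gave p = 0.0089 for the 200 genes on each side, and the rest of the arm was not tested by rotation). Genes of the arm as a whole were not easier to call, since the odds ratio for starvation calls in controls was 0.995. Within 200 genes of chm starvation calls were more frequent, at 17.8% against 12.1% elsewhere in controls and 16.5% against 11.1% in mutants, a smaller rise than that of genotype calls (3.75% against 0.327% on other arms). A candidate explanation is strain variation carried along with the chm mutation on 2L, and an action of chm on genes of its own arm was not tested and stays open.

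Mutant starved replicate 2 lay toward the controls on part of 2L. Positions were put on a scale from 0 (control) to 1 (mutant), for genes picked in the fed libraries only. On it, mutant starved replicate 2 stood at 1.16 before chm (6 genes), 1.27 for chm itself and 0.825 on other arms (8 genes). Control starved libraries ran from -0.332 to 0.272 before chm. On other arms they ran from -0.811 to 0.719, near mutant starved replicate 1 at 0.722. That last position therefore says little about genotype. After chm (15 genes) mutant starved replicate 2 stood at -0.0974, where the other mutant starved libraries stood at 1.12 to 1.91. Control starved libraries were themselves spread from -0.604 to 0.441 there. The gap from mutant starved replicate 2 to its nearest replicate did not take more than 0.71 of the range of its group. By that measure the library was not set apart. The values before chm argue against a wrong label or control flies in the sample. Its difference of 1.26 between the sides of chm, against -0.891 to -0.173 in the others, may come from a different 2L haplotype beyond chm, a hypothesis that these counts cannot test at the level of DNA. On a like scale for fed libraries, with genes picked in the starved libraries only, mutant fed replicate 2 was also the lowest of its group after chm. It stood at 0.582 against 0.824 to 1.34, so the shift is not shown to belong to 1 library alone. Without mutant starved replicate 2, 98 genes were called in starved flies, 64 of 96 placed genes other than chm on 2L, an alternative chosen after seeing the data.

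Fat body markers fell with starvation, and most of the loss in their share of counts was that of Lsp2 (1.71 to 0.215% in controls, 1.65 to 0.270% in mutants). In a measure chosen after the share was seen, the other 10 markers took 2.43 ± 0.162% in control fed and 1.74 ± 0.158% in control starved libraries, and 2.37 ± 0.143 and 1.68 ± 0.146% in mutants. The markers did not fall by 1 common amount, since the 11 log2 fold changes in controls had an SD of 1.42, against a median SE of 0.0647, and ran from fit at -4.54 to Apoltp at -0.16. That argues against a lower share of fat body RNA as the sole cause only if every marker comes from fat body alone, which was not tested. A part played by tissue share, beside regulation of single genes, stays open.

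The libraries of each comparison were refitted under 100 splits, the real one included, without the libraries of the other groups. For starvation, no split other than the real one gave as many calls in either genotype. Controls had 1093 real calls and at most 115 in another split, and mutants had 1125 and 3. Other mutant splits parting all 5 pairs gave at most 0. A count of 1 in 100, the real split, is the smallest possible here, so chance is unlikely but not excluded outright. For genotype in fed flies 2 splits gave as many, the real one included (30 real, 42 highest other). That other split had control fed replicates 1, 4 and 5 and mutant fed replicates 1 and 4 on one side. In starved flies 3 splits did, the real one included (39 real, 189 highest other, then 82). The splits were drawn without regard to run and lane, which the real split balances and the fit includes. Splits that partly follow run and lane have less power to call genes. The split with 42 calls was balanced like the real one, so the splits do not exclude chance for genotype. The split with 189 calls, several times the real count, points to a structure of the samples. It set control starved replicates 1 to 3 and mutant starved replicates 1 and 2 against the rest. With run and lane in the fit, it rests on control starved replicate 3 against the other 3 libraries of lane 3. Splits that put control starved replicate 4, mutant starved replicate 4 or mutant starved replicate 5 in its place gave 0 calls (edgeR). In the fit of all groups, where the real comparison gave 32 calls, it gave 15 without control starved replicate 3. Leaving out control starved replicate 4 or mutant starved replicate 4 instead also gave 15, so that drop is not particular to control starved replicate 3. Fits within the lanes gave 18 and 63. The split with 82 calls, 57 on 2L, exchanged control starved replicate 5 and mutant starved replicate 2, and a split of fed flies with 27 calls, 24 on 2L, exchanged control fed replicate 5 and mutant fed replicate 2. For the difference between responses the real count was 0 in these fits, which had the replicate number as a block (edgeR; 19 highest other). A count of 0 is matched by any split, here 100 of 100, so the splits say nothing about that comparison.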
